A study of Homo sapiens with 30 samples.

How the data were processed

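The series measured gene expression in primary human bronchial epithelial cells of 3 donors on 11 days, 0 through 28, of air-liquid interface culture, with 30 samples and 1 array per sample. Per the labels' protocols, the cells were expanded to passage 3, plated on coated filters in 12-well plates and treated with 500 nM retinoic acid once 100% confluent. The upper medium was removed 48 hours later, which is day 0, and the medium below held 100 nM retinoic acid from then on. Per the labels' protocols, total RNA was extracted and biotin-labelled cRNA was hybridized to the arrays.

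The values analysed were the authors' deposited table of intensities, 1 column per array and 1 row for each of 54675 probe sets. Per the submitters' processing notes they were made with RMA, which corrects background, normalizes arrays by quantiles and summarises the probes of a probe set; its version was not given in the sources used here. RMA gives log2 values, and the deposited intensity values were on a linear scale, between 7.3 and 24883.7, so log2 was taken before any test, with no offset. Quantile normalization before summary gives the arrays almost the same distribution, which removes differences in overall signal between days, so changes here are relative to the other genes of an array. Median intensities per array lay between 89.8 and 101. Correlations between arrays lay between 0.954 and 0.997 over the probe sets on the log2 scale, and no 2 arrays held identical values. For arrays, their number limits the precision, with 2 or 3 donors per day.

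Probe sets were named through the platform annotation given for this work. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none listed, and none was named from several symbols. Of the named probe sets, 40950 matched a gene by Entrez identifier in a RefSeq gene table, and 0 symbols needed an update. Another 93 named probe sets were left out because their genes are linked to sex or are commonly deleted or highly variable between people. No genome coordinates were used. Of several probe sets of a gene, the one with the highest mean over all arrays was taken. A gene was kept if its value was above the 40th percentile of all values of the table (log2 6.05, intensity 66.1) on at least 2 arrays, which left 16036 of 19726 genes.

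Samples were grouped by the day in their titles, and the donor number in the titles named the replicate. Day 28 replicate 3 is described as day 18 in another label, and the day in its title was used. Each comparison came from 1 fit of 11 day groups over all 30 arrays with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the genes tested and an adjusted p threshold of 0.05. The fit had 19 residual degrees of freedom. The comparisons were day 28 with day 0, day 1 with day 0, day 4 with day 1, day 8 with day 4, day 14 with day 8 and day 28 with day 14, all days with 3 donors, besides a moderated F test over all days. A gene was called as peaking or dipping when the mean of days 4, 8 and 10 differed from day 0 and from day 28 in the same direction, both past the threshold.

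Donor was not part of the main fit and was added as a fixed block in an alternative. The main fit therefore ignores the pairing by donor and leaves differences between donors in the spread. The same donor number means the same donor, per the labels, so the numbers pair the samples. Deviations from the day means correlated with a median of 0.354 over 138 pairs of arrays of the same donor (range -0.01 to 0.83) and -0.187 over 270 pairs of different donors, and 30 of 30 arrays correlated best with an array of their own donor.

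The 26 gene lists were fixed from general knowledge of airway epithelium before the data were examined, and 3 of them hold markers of other cell types. They were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over all 156 tests of a list in a comparison, and again with a correlation estimated per list. Of 65 calls, 4 held with an estimated correlation: S phase from day 1 to day 4, hypoxia and glycolysis from day 0 to day 1 and from day 0 to day 28, and the retinoic acid response from day 8 to day 14. With an estimated correlation and the donor block none of these 4 held. No called list had a median, mean and test that differed in sign. For the course of a list over days, the log2 values of its measured genes minus those of the same donor on day 0 were averaged.

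The rule for named genes was fixed before the data were examined. It took the 12 largest rises and falls from day 0 to day 28 among genes past the threshold and moved the same way in all 3 donors, the 5 largest rises and falls in each other comparison, and the 6 genes that peaked or dipped most. From each list it took up to 2 rises and 2 falls, or the members with the highest mean level where fewer than 2 passed, and 14 genes of airway cell types were given whatever their result. A further gene fixed in advance had no probe set assigned to it alone and was not analysed here.

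Alternatives were the donor block (fixed or random), quantile normalization, centring of each array on the median, no filter on dim genes or a filter at the 60th percentile, the mean of all probe sets of a gene, every probe set by itself, eBayes with trend and robust options, array quality weights, a 2-fold threshold, only the days compared, an offset of 16, and leaving out each donor or array. For lists they were camera with an estimated correlation, fry, and lists without shared genes.

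The code was tested on simulated data. In 16036 simulated genes, 200 were changed on days 14, 21 and 28. The donor differences of the real genes were reassigned among genes and held constant over days. Noise of the real spread was added independently for each gene. Real genes are correlated and real donors also differed by day, so the rates below may not carry over. For day 28 against day 0, limma without the block recovered 40% of changes of 0.5, 96% of changes of 1 and 100% of changes of 2 and 4 on the log2 scale, each among 50 genes, with 2 false calls. With the block, 58%, 98%, 100% and 100% were recovered with 9 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.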

Results

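Gene expression was measured with 1 oligonucleotide array per sample in human bronchial epithelial cells from 3 donors, collected on 11 days of culture between day 0 and day 28. The cells were grown on porous filters, and from day 0 their upper surface was exposed to air while medium reached them from below. This air-liquid interface culture is used to study how airway epithelial cells differentiate into ciliated and secretory cells. Days 0, 1, 4, 8, 10, 14, 21 and 28 had samples of all 3 donors, and days 2, 12 and 17 had samples of 2 donors, which makes 30 arrays. Each array gave an intensity for 54675 probe sets, and the median intensity per array lay between 89.8 and 101. The number of arrays limits the precision of every value below. After probe sets were assigned to genes and dim genes were left out, 16036 genes were tested with limma on log2 intensities. Changes are log2 differences ± SE from the fit over all 30 arrays, with 3 donors on each day compared, and adjusted p-values are limma's with Benjamini-Hochberg adjustment.

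Between the start and the end of the culture, the lists of motile cilia and secretory genes were higher, and those of hypoxia and glycolysis, the cell cycle, squamous epithelium and matrix were lower, most of them with part of their genes. With an estimated correlation only the hypoxia list of these kept its call (adjusted p = 0.0237, against at least 0.0918 for the others), and it lost it with the donor block as well (adjusted p 0.0984). The comparison of day 28 with day 0 asks what distinguished the long-term culture from cells just exposed to air. BPIFB1 and BPIFA1, which encode secreted proteins of the airway surface, rose by 7.85 ± 0.36 and 7.46 ± 0.21, or at least 231-fold and 177-fold. SCGB3A1, a secretoglobin, rose by 6.92 ± 0.40, STATH, a salivary and airway secretory protein, by 6.74 ± 0.47, and CYP2F1, an airway cytochrome P450, by 6.81 ± 0.40. PROM1, a membrane protein of cell protrusions, rose by 6.85 ± 0.35. Of genes tied to ciliated cells, SNTN, a protein of the ciliary tip, rose by 6.78 ± 0.88, CDC20B by 6.52 ± 0.62, TPPP3 by 6.19 ± 0.82 and CIMIP1 by 5.96 ± 0.74. HLA-DRA, the alpha chain of an MHC class II molecule, rose by 6.06 ± 0.33 and AGR3 by 5.90 ± 0.82. All 12 rises, picked among genes that moved the same way in all 3 donors, had an adjusted p of at most 6.15e-06. On day 28 SCGB3A1 was the brightest probe set of all 3 arrays, and BPIFB1 and BPIFA1 lay within 0.16 and 0.24 of the brightest. Their probe sets may therefore have been near saturation. On day 0, 6 of the 12 genes were at or below the limit for dim genes (log2 6.05) on all 3 arrays, and TPPP3 and HLA-DRA, with means of 5.95 and 6.05, on 2 of them. Changes of genes at either limit are given as lower bounds, since such signals may be compressed. Here and below such a bound concerns compression only, and within the error given by the SE the true change may be smaller. The limit for dim genes is the filter setting, and neither background nor saturation was measured.

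LOXL2, a lysyl oxidase that cross-links matrix, had the largest fall named for this comparison, at -5.70 ± 0.33. KLK6, KLK7, KLK5 and KLK8, kallikrein proteases found in cornifying epithelium, fell by 5.11 ± 0.37, 4.63 ± 0.72, 4.26 ± 0.47 and 3.97 ± 1.06. RHCG, an ammonia transporter, fell by 4.93 ± 0.80 and COXFA4L2 by 4.42 ± 0.49. ANGPTL4, a hypoxia-responsive regulator of lipoprotein lipase, fell by 4.16 ± 0.21. CYP26B1, a retinoic acid-degrading enzyme, fell by 3.76 ± 0.39. AKAP12, LGALS1 and TMEM156 fell by 4.39 ± 0.30, 4.11 ± 0.23 and 3.73 ± 0.34. The highest adjusted p among these 12 falls was 0.00516, for KLK8. CYP26B1 and TMEM156 were below the limit for dim genes on all 3 arrays of day 28, so their falls are lower bounds too. In all, 5753 of 16036 genes passed, 2839 higher and 2914 lower on day 28, and 1471 of them changed at least 2-fold. Without replicate 2, 2531 genes passed. With each array centred on its median, the share of calls that were higher was 37.6% in place of 49.35%, and the median change of all genes moved from -0.02 to -0.11.

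The ciliary axoneme list had the largest median change of the 26 lists from day 0 to day 28. Of 106 measured genes of the ciliary axoneme list, 87 rose, 2 fell and 17 did not pass, with a median change of 2.17; adjusted over the list alone, 92 rose and 2 fell. The list test (camera with a preset correlation) gave an adjusted p of 1.03e-19, against an adjusted p = 0.48 with an estimated correlation. DNAI1, a dynein chain of the ciliary motor, rose by at least 2.22 ± 0.41, from the limit for dim genes, and TEKT1, a protein of ciliary microtubules, by 2.95 ± 0.63. The 2 members that fell were SPMIP8 at -0.53 ± 0.18, which was below the limit for dim genes on day 28, and CFAP73 at -0.30 ± 0.09, and another probe set of CFAP73 was called in the opposite direction. Of 39 intraflagellar transport genes, which carry cargo along cilia, 29 rose and 10 did not pass, with IFT57 at 2.01 ± 0.41 and IFT88 at 1.80 ± 0.42 (adjusted p 4.85e-07, against adjusted p = 0.646 with an estimated correlation). Of 19 regulators of ciliated cells, 8 rose and 1 fell; FOXJ1, the transcription factor of motile cilia, rose by 3.34 ± 0.56 and CCDC78, a protein of centriole multiplication, by at least 3.91 ± 0.78, while TFDP1 fell by 0.23 ± 0.08 (list adjusted p 0.00057, against adjusted p = 0.591 with an estimated correlation). The call of TFDP1 was lost with quantile normalization (-0.09, adjusted p 0.208). With p-values adjusted over the list alone, 29 intraflagellar transport genes and 8 regulators rose.

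Secretory genes went both ways. Of 49 measured members, 23 rose and 6 fell, or 24 and 6 adjusted over the list alone (adjusted p 2.36e-05, against adjusted p = 0.3 with an estimated correlation). MUC5B, a gel-forming mucin, rose by at least 2.34 ± 0.77 from below the limit for dim genes (adjusted p 0.0202), and the other gel-forming mucin, MUC5AC, rose by 0.50 ± 0.14 on its brightest probe set, a call lost over the mean of its probe sets (0.07, adjusted p 0.609). CLCA4 fell by 1.59 ± 0.42, GALNT5 was 2.84-fold lower, and SPDEF, a transcription factor of goblet cells, fell by 1.03 ± 0.33. SCGB1A1, the club cell secretoglobin, had a change of -0.98 ± 0.46 that did not pass (adjusted p 0.103); its mean log2 intensity was 12.10 ± 0.86 (SD, n = 3) on day 0 and 11.12 ± 0.93 on day 28.

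Basal and squamous genes fell in part. Of 32 basal genes, 22 fell and 1 rose, and 23 fell adjusted over the list alone (adjusted p 3.34e-07, against adjusted p = 0.267 with an estimated correlation). IGFBP6 fell by 3.49 ± 0.43 and THBS1, a matrix glycoprotein, by 2.78 ± 0.38, while DAPL1 rose by 2.42 ± 0.37. KRT5, the keratin of basal cells, fell by 0.30 ± 0.10 (adjusted p 0.0171), a call lost with quantile normalization (-0.21, adjusted p 0.0599). It stood at 13.83 ± 0.25 (SD, n = 3) on day 28. In donor 3 it did not fall, with 14.09 on day 0 and 14.12 on day 28. On day 0 its probe set lay within 0.19 to 0.35 of the brightest of each array, so the size of its change is uncertain. KRT14 had a change of -0.37 ± 0.60 and did not pass (adjusted p 0.672). Of 53 squamous and cornified genes, 23 fell and 3 rose, and 25 fell adjusted over the list alone (adjusted p 4.77e-05, against adjusted p = 0.69 with an estimated correlation). SPRR1B, a cornified envelope protein, fell by 1.45 ± 0.52, RPTN rose by at least 2.38 ± 0.86 and SERPINB3, bright on day 28, by at least 0.90 ± 0.23, and KRT4 had a change of -0.34 ± 0.36 that did not pass. The mean change of the squamous list from a donor's own day 0 to day 28 lay between -2.12 and 0.10 over the donors.

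**Figure D1:**
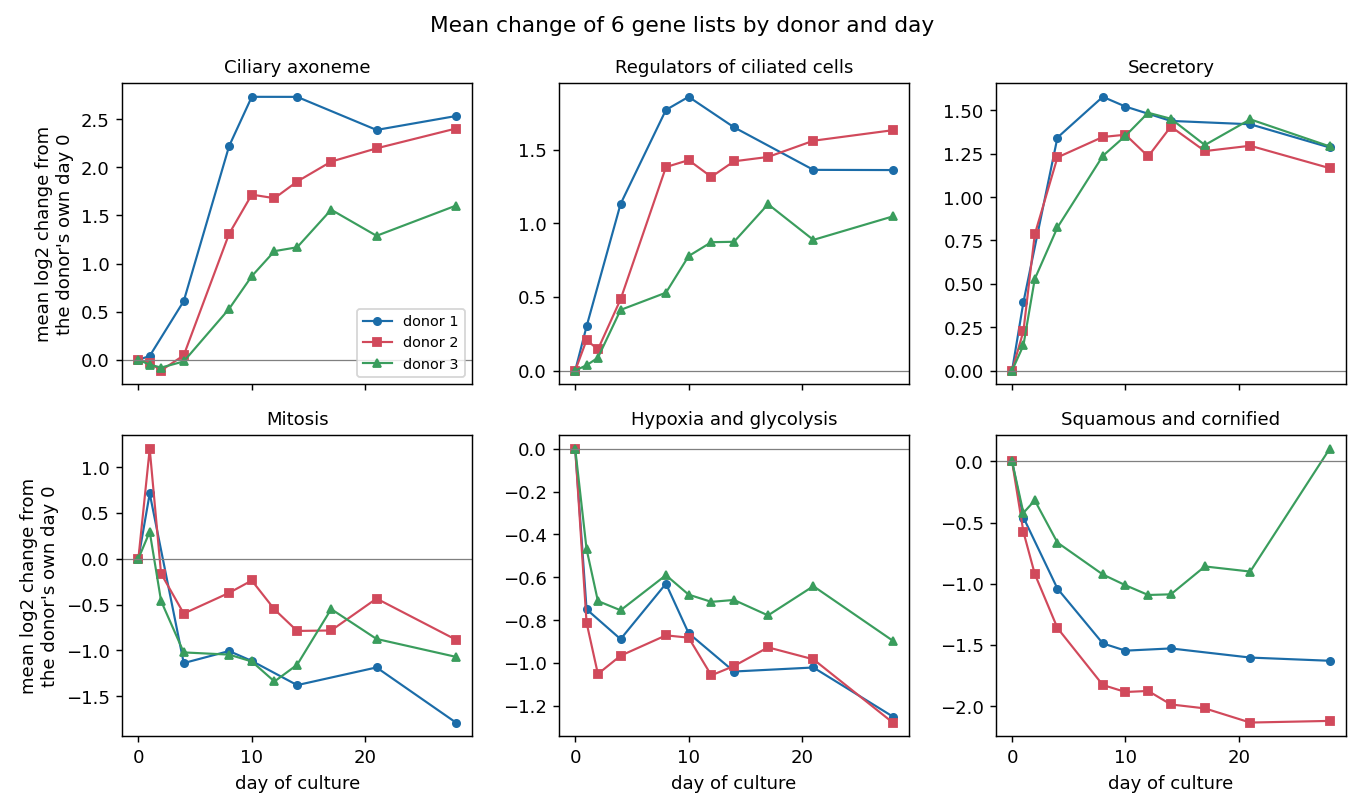
Mean log2 change of the measured genes of 6 lists (y axis) by day of culture (x axis), each donor against its own day 0, with 1 point per array and 1 line per donor. The axoneme list stood at 0.21 ± 0.35 (SD, n = 3) on day 4, 1.35 ± 0.85 on day 8 and 2.18 ± 0.50 on day 28, and the mitosis list at 0.74 ± 0.45 on day 1 and -0.92 ± 0.28 on day 4.

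Hypoxia and glycolysis genes fell almost throughout the list: 42 of 48 fell and 1 rose, and 43 fell adjusted over the list alone (adjusted p 7.61e-25, and adjusted p = 0.0237 with an estimated correlation, but 0.0984 with an estimated correlation and the donor block). ALDOC, a glycolytic aldolase, fell by 3.22 ± 0.19, while LOX, a lysyl oxidase, rose by 1.15 ± 0.31. That call of LOX was lost over the mean of its probe sets (0.65, adjusted p 0.0881). Of 26 cholesterol biosynthesis genes, 21 fell and 1 rose, with the desaturase FADS2 at -3.19 ± 0.24, the sterol carrier STARD4 at -2.40 ± 0.20 and PMVK at 0.46 ± 0.09 (adjusted p 5.55e-09, against adjusted p = 0.33 with an estimated correlation). Of 57 mitosis genes, 46 fell, among them ASPM by at least 2.49 ± 0.37 and BUB1B by 2.13 ± 0.39, and MKI67, a proliferation marker, fell by 0.96 ± 0.15 (list adjusted p 1.39e-15, against adjusted p = 0.441 with an estimated correlation). Of 43 S-phase genes, 16 fell and 1 rose, with RRM2 and TYMS, enzymes of nucleotide synthesis, at -1.95 ± 0.28 and -1.77 ± 0.28 and POLA1 at 0.77 ± 0.19 (adjusted p 0.00313, against adjusted p = 0.721 with an estimated correlation). Adjusted over the list alone, 21 cholesterol, 48 mitosis and 17 S-phase genes fell.

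Part of the matrix and mesenchymal genes, immediate early genes and ribosomal protein genes fell too. Of 38 matrix and mesenchymal genes, 20 fell, among them the tropomyosin TPM2 by 2.44 ± 0.23, and 1 rose, CCN2, a matricellular growth factor, by 3.96 ± 0.77 (adjusted p 1.04e-06, against adjusted p = 0.0918 with an estimated correlation). Of 32 immediate early genes, 14 fell and 4 rose, with FOS at -2.39 ± 0.24, PHLDA1 at -2.65 ± 0.46 and ATF3 at 1.33 ± 0.43 (adjusted p 0.00603, against adjusted p = 0.568 with an estimated correlation). Of 44 ribosomal protein genes, 17 fell, with RPL36 at -0.50 ± 0.08 and RPS21 at -0.37 ± 0.08 (adjusted p 0.000326, against adjusted p = 0.704 with an estimated correlation). Over the mean of its probe sets ATF3 had a change of 0.48 and was not called (adjusted p 0.0503). RPS21 had a larger change there, -0.52, and was not called either (adjusted p 0.0803). The interferon list was higher: 27 of 47 genes rose and 1 fell, with IFI6 at 2.33 ± 0.34, IFI44 at 1.98 ± 0.23 and ISG20 at -0.71 ± 0.15 (adjusted p 1.76e-07, against adjusted p = 0.3 with an estimated correlation). Adjusted over the list alone, 23 matrix, 16 immediate early and 17 ribosomal protein genes fell, and 28 interferon genes rose and 2 fell.

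With camera at the preset correlation, further lists were not called from day 0 to day 28 although some of their genes changed. Of all genes tested, 17.7% were called higher and 18.2% lower in this comparison. Of 54 xenobiotic metabolism genes, 24 rose and 16 fell, with the glutathione transferase GSTA1 at 4.84 ± 0.29, GPX3 at -2.56 ± 0.35 and AKR1B10 at -2.47 ± 0.29 (adjusted p 0.079). Of 40 ion and water transport genes, 12 rose and 8 fell, with the phosphate transporter SLC34A2 at 3.97 ± 0.51, the water channel AQP5 at 3.02 ± 0.66, the carbonic anhydrase CA2 at -3.38 ± 0.48 and FXYD5 at -2.80 ± 0.23 (adjusted p 0.614). CFTR, the chloride channel mutated in cystic fibrosis, had a change of 0.45 ± 0.29 that did not pass (adjusted p 0.231), while 1 other of its 6 probe sets was called as a rise. Of 25 retinoic acid response genes, 12 fell and 3 rose, with the retinal dehydrogenase ALDH1A1 at 4.16 ± 0.30, PLAAT4 at 1.30 ± 0.23, NRIP1 at -1.89 ± 0.26 and CYP26A1, which degrades retinoic acid, at -1.15 ± 0.37 (adjusted p 0.0977). Of 39 inflammatory genes, 14 fell and 3 rose, with EREG at -3.34 ± 0.37 or lower, IL1B at -2.47 ± 0.37, CXCL1 at 0.88 ± 0.25 and RELB at 0.86 ± 0.17 (adjusted p 0.0705, but 0.0257 and called lower without day 28 replicate 3, against adjusted p = 0.782 with an estimated correlation). Of 37 tight junction and polarity genes, 10 rose and 8 fell, with CDHR3 at 3.37 ± 0.85 or higher, ESRP1 at -0.94 ± 0.13 and TJP1 at -0.67 ± 0.12 (adjusted p 0.454).

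Of 34 unfolded protein response genes, 6 rose and 11 fell from day 0 to day 28, with the transcription factors XBP1 at 1.48 ± 0.16 and CREB3L1 at 1.43 ± 0.22, TRIB3 at -1.42 ± 0.41 and MANF at -0.88 ± 0.12 (list adjusted p 0.696). Of 32 Notch pathway genes, 5 rose and 11 fell, with HES6 at 1.24 ± 0.27, HEY2 at 0.70 ± 0.17, the receptor NOTCH3 at -1.23 ± 0.14 and HES2 2.83-fold lower (list adjusted p 0.338). Of 55 oxidative phosphorylation genes, 12 rose and 4 fell, with NDUFA5 at 0.68 ± 0.13, NDUFA8 at 0.66 ± 0.21, NDUFS4 at -0.51 ± 0.11 and NDUFS7 at -0.50 ± 0.13 (list adjusted p 0.0547). Of 14 genes of ionocytes, tuft and neuroendocrine cells, 5 rose and 1 fell, with the proton pump subunit ATP6V1B1 at 2.57 ± 0.34, PCSK1N at 1.70 ± 0.29 and UCHL1 at -0.39 ± 0.11 (list adjusted p 0.28). UCHL1 lost its call over the mean of its probe sets (-0.15, adjusted p 0.18). Adjusted over the list alone, the numbers that rose and fell were 26 and 17 for xenobiotic metabolism, 12 and 9 for ion and water transport, 3 and 12 for the retinoic acid response, 4 and 16 for inflammatory genes, 12 and 8 for tight junctions, 8 and 12 for the unfolded protein response, 6 and 11 for the Notch pathway, 11 and 3 for oxidative phosphorylation and 5 and 1 for the rare cell types.

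Marker lists of other cell types were not called with camera at the preset correlation in this comparison. Of 14 leukocyte genes, ITGB2 rose by 0.77 ± 0.29 and 3 fell, among them CD14 by 1.40 ± 0.23 and CORO1A by 1.14 ± 0.15 (list adjusted p 0.51). The 7 fibroblast genes gave no call with limma, with COL1A1 at -0.05 ± 0.11, DCN at 0.17 ± 0.25, PDGFRB at -0.06 ± 0.12 and THY1 at -0.25 ± 0.10 (adjusted p 0.0586 for THY1, 0.0231 with the donor block, and 0.929 for the list). At an unadjusted p under 0.05, 1 of the 7 were lower and 0 higher. Of 7 endothelial and erythroid genes 1 fell, and the brightest were HBB at 0.15 ± 0.10, PECAM1 at -0.06 ± 0.10, VWF at -0.25 ± 0.13 and CLDN5 at 0.16 ± 0.16, none of which passed (list adjusted p 0.958). COL1A1 had 2 other probe sets called as falls and HBB 3 called as rises. Over the mean of its probe sets COL1A1 was called lower (-0.65, adjusted p 0.0171) and HBB higher (0.83, adjusted p 0.00713), and with centred arrays VWF was called lower (adjusted p 0.0472). THY1 was called lower with quantile normalization (-0.25, adjusted p 0.0466) and with centred arrays (-0.33, adjusted p 0.0429). Adjusted over the list alone, the leukocyte list gave 1 rise and 3 falls, and the fibroblast list and the endothelial and erythroid list gave 0 calls with limma, with 1 gene each lower at an unadjusted p under 0.05. The 3' minus 5' difference of the GAPDH control probe sets, a measure of RNA integrity, was -0.07 ± 0.04 on the log2 scale (SD, n = 3) on day 0 and 0.13 ± 0.12 on day 28, and that of ACTB was 0.04 ± 0.05 and 0.25 ± 0.12.

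**Figure D2:**
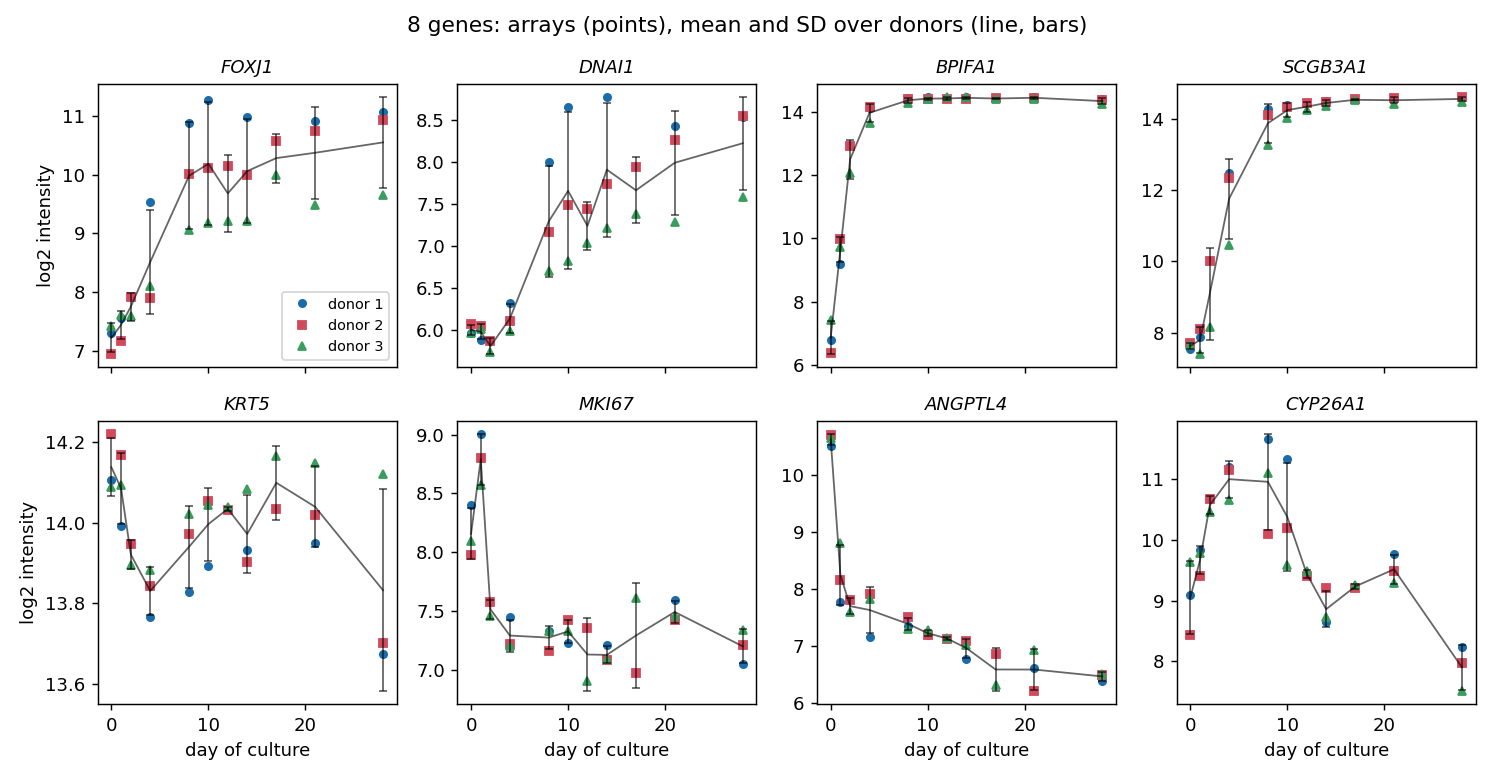
Log2 intensity (y axis) of 8 genes by day of culture (x axis), with 1 point per array coloured by donor, and the mean and SD over the 2 or 3 donors of each day as a line with bars. FOXJ1 stood at 7.22 ± 0.25 on day 0, 9.98 ± 0.91 on day 8 and 10.55 ± 0.78 on day 28, and CYP26A1 at 9.05 ± 0.60, 10.96 ± 0.79 and 7.90 ± 0.37.

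After the first day in air, the cell cycle lists were higher and the hypoxia and glycolysis list was lower. Of the 3, the hypoxia list alone kept its call with an estimated correlation (adjusted p = 0.0302, against 0.0851 and 0.405). BPIFA1 already rose by 2.77 ± 0.21 from day 0 to day 1, followed by CXCL5, a neutrophil-attracting chemokine, at 2.47 ± 0.78, PLEKHS1 at 2.25 ± 0.26, SPC25, a kinetochore protein, at 1.99 ± 0.26 and SLC34A2 at 1.93 ± 0.51. The falls named were ANGPTL4 at -2.38 ± 0.21, the receptor KISS1R at -2.18 ± 0.24, ADSS1 at -2.16 ± 0.19, EGLN3, a hypoxia-induced prolyl hydroxylase, at -2.04 ± 0.24 and PPP1R3C, a regulator of glycogen synthesis, at -2.02 ± 0.26. CXCL5 had the highest adjusted p of these 10 genes, 0.0362, and its call was lost over the mean of its probe sets (1.56, adjusted p 0.0606). CXCL5, PLEKHS1 and SPC25 on day 0 and KISS1R on day 1 were at or below the limit for dim genes on at least 2 arrays, so their changes are lower bounds. Of 43 S-phase genes 31 rose (37 adjusted over the list alone, list adjusted p 5.73e-29, against adjusted p = 0.0851 with an estimated correlation). Of 57 mitosis genes 26 rose (32 adjusted over the list alone, list adjusted p 1.36e-16, against adjusted p = 0.405 with an estimated correlation). Of 48 hypoxia and glycolysis genes 30 fell (38 adjusted over the list alone, list adjusted p 2.74e-22, and adjusted p = 0.0302 with an estimated correlation, but 0.0984 with the donor block as well).

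The lists of the unfolded protein response, interferon response and secretory genes were higher on day 1, with 9 of 34, 3 of 47 and 7 of 49 genes that rose and 0, 0 and 3 that fell. Their adjusted p-values were 5.02e-06, 0.00275 and 0.0467, against adjusted p = 0.33, 0.609 and 0.646 with an estimated correlation. The call of the secretory list was lost with genes on 1 list only (adjusted p 0.117) and without day 28 replicate 3 (adjusted p 0.0535). Adjusted over the list alone, 11, 0 and 7 of these genes rose, with 14 interferon genes higher at an unadjusted p under 0.05. Squamous genes, 4 of 53 of which fell, and tight junction genes, 7 of 37 of which fell and 1 rose, were lower as lists (adjusted p 0.00746 and 0.00771, against adjusted p = 0.828 and 0.591 with an estimated correlation). The call of the squamous list was lost without day 1 replicate 1 (adjusted p 0.122). The numbers that fell adjusted over the list alone were 4 squamous and 10 tight junction genes. The matrix list was called lower only with the donor block, with 2 of 38 genes that fell and 1 that rose without it (adjusted p 0.129, and 0.0274 with the block, against adjusted p = 0.413 with an estimated correlation and the block). In all, 2099 genes passed between day 0 and day 1, 1149 higher and 950 lower, and 3221 passed with donor as a block, but only 70 without replicate 2, 33 higher and 37 lower. Without day 0 replicate 2 or day 1 replicate 2, 1345 and 1368 genes passed, and 1690 passed without day 1 replicate 1, whose bacterial control probe sets lay 1.48 above the median of the other arrays on the log2 scale.

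On day 4 the secretory list was higher than on day 1, with part of its genes, and the cell cycle lists were lower. Only the S-phase list kept its call with an estimated correlation (adjusted p = 0.0237, against 0.0584 for mitosis and 0.0621 for secretory genes). CDC20B, which lies among the genes of centriole multiplication, rose by 6.20 ± 0.62, BPIFB1 by 4.69 ± 0.36, BPIFA1 by 4.32 ± 0.21, SCGB3A1 by 3.96 ± 0.40 and TOX3 by 3.22 ± 0.54. Of the 5 probe sets of CDC20B, only the brightest was called in this interval. SHCBP1 fell by 2.98 ± 0.30, RRM2 by 2.72 ± 0.28, the mitotic kinase PBK by 2.71 ± 0.33, and the kinetochore genes NDC80 and SPC25 by 2.67 ± 0.37 and 2.67 ± 0.26. CDC20B and TOX3 on day 1 and SHCBP1, NDC80 and SPC25 on day 4 were at or below the limit for dim genes on at least 2 arrays, which makes their changes lower bounds. BPIFA1 lay within 0.16 to 0.57 of the brightest probe set of each array on day 4, so its rise is a lower bound too. Of 57 mitosis genes 53 fell (55 adjusted over the list alone, list adjusted p 2.83e-63, against adjusted p = 0.0584 with an estimated correlation). Of 43 S-phase genes 36 fell (39 adjusted over the list alone, list adjusted p 3.79e-49, and adjusted p = 0.0237 with an estimated correlation, but 0.0546 with the donor block as well). Of 49 secretory genes 16 rose (20 adjusted over the list alone, list adjusted p 1.22e-10, against adjusted p = 0.0621 with an estimated correlation). Of 106 axoneme genes 1 fell and 105 did not pass, with a median change of 0.16 (list adjusted p 0.868).

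The interferon, xenobiotic metabolism, retinoic acid response and tight junction lists were higher on day 4 than on day 1, with 16 of 47, 13 of 54, 6 of 25 and 7 of 37 genes that rose, or 17, 18, 10 and 7 adjusted over the list alone, and 1 xenobiotic metabolism gene that fell. Their adjusted p-values were 1.61e-07, 0.00021, 0.00462 and 0.00623, against adjusted p = 0.3, 0.354, 0.0918 and 0.579 with an estimated correlation. The oxidative phosphorylation list, in which 3 of 55 genes rose, was called higher without the donor block (adjusted p 0.02) and not with it (adjusted p 0.0569), and the adjusted p was 0.879 with an estimated correlation. The cholesterol, hypoxia, squamous and basal lists were lower, with 7 of 26, 13 of 48, 4 of 53 and 1 of 32 genes that fell, or 9, 19, 3 and 1 adjusted over the list alone. In the hypoxia and basal lists 1 gene each rose. Their adjusted p-values were 1.02e-08, 5.97e-07, 3.61e-05 and 0.00311, against adjusted p = 0.33, 0.322, 0.69 and 0.568 with an estimated correlation. The ribosomal protein list (median change -0.04, adjusted p 0.025) and the immediate early list (median -0.14, adjusted p 0.046) were called lower, against adjusted p = 0.851 and 0.69 with an estimated correlation. The matrix list was called lower only with the donor block or without day 1 replicate 1 (adjusted p 0.0611, 0.0361 with the block and 0.0313 without the array, against adjusted p = 0.414 with an estimated correlation and the block). The unfolded protein response list was called lower with genes on 1 list only (adjusted p 0.00284). The ion and water transport list was called higher without day 1 replicate 1 (adjusted p 0.0466). With an estimated correlation their adjusted p-values were 0.765 and 0.656. In all, 1563 genes passed, 939 higher and 624 lower, and 2896 with donor as a block, but 251 without replicate 2. Centring each array on its median gave 792 higher and 825 lower, and 955 and 961 genes passed without day 4 replicate 2 or day 1 replicate 3.

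From day 4 to day 8 the ciliary axoneme list was higher (adjusted p = 0.317 with an estimated correlation) while few single genes passed without the donor block. The 5 genes that passed were PROM1 at 2.68 ± 0.35, AZGP1, a secreted glycoprotein, at 1.53 ± 0.24 or higher, BMP7, a growth factor, at 0.80 ± 0.13, TCTA at 0.75 ± 0.12 and the GTPase RHOF at -0.93 ± 0.13. The axoneme list had a median change of 1.15, with 103 of 106 genes above 0. Adjusted over all genes, limma called none of these genes, while 31 rose adjusted over the list alone, 37 rose with donor as a block, and 57 were higher at an unadjusted p under 0.05 (list adjusted p 6.22e-32, against adjusted p = 0.317 with an estimated correlation). The intraflagellar transport list (median 0.38, adjusted p 6.88e-07), the regulators of ciliated cells (median 0.49, adjusted p 0.000222), the hypoxia list (median 0.13, adjusted p 7.07e-05) and the secretory list (median 0.13, adjusted p 0.0279) were also higher, against adjusted p = 0.646, 0.568, 0.464 and 0.609 with an estimated correlation. The call of the secretory list was lost with genes on 1 list only (adjusted p 0.0545). Cholesterol (median -0.25, adjusted p 1e-05), matrix (median -0.20, adjusted p 0.000397), squamous (median -0.23, adjusted p 0.00121) and interferon (median -0.14, adjusted p 0.019) lists were lower, against adjusted p = 0.547, 0.3, 0.765 and 0.69 with an estimated correlation. The inflammatory list was called lower only with the donor block or without day 28 replicate 3 (adjusted p 0.0561, 0.0463 with the block and 0.0484 without the array, against adjusted p = 0.784 with an estimated correlation and the block).

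With donor as a block, 271 genes passed between day 4 and day 8, 187 higher and 84 lower, against 4 higher and 1 lower without it. The count rested on single arrays: it was 28 without day 4 replicate 1, 34 without day 8 replicate 3, 3 without day 4 replicate 2 or day 4 replicate 3, and 1 without day 8 replicate 1. Without replicate 2 limma called 0 genes, with 583 at an unadjusted p under 0.05. BMP7 and RHOF lost their calls over the mean of their probe sets (0.52 and -0.47, adjusted p 0.0986 and 0.178).

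From day 8 to day 14 the retinoic acid response list was lower. CYP26A1 fell by 2.10 ± 0.37 (adjusted p 0.0475), GDF15, a stress-induced cytokine, by 1.67 ± 0.22 (adjusted p 0.00227) and RHOF by 0.81 ± 0.13 (adjusted p 0.0208). CYP26A1 was the 1 gene of 25 in the retinoic acid list that passed, and 5 fell adjusted over the list alone (list adjusted p 1.39e-06, and adjusted p = 0.0115 with an estimated correlation, but 0.0546 with the donor block as well). CYP26A1 has 1 probe set, and its change stayed at -2.10 over the mean of probe sets and with the trend and robust options of eBayes, while its adjusted p rose past the threshold (0.073 and 0.0693). The hypoxia (median -0.20, adjusted p 6.1e-15), inflammatory (median -0.41, adjusted p 6.14e-12) and mitosis (median -0.33, adjusted p 5.56e-09) lists were lower, against adjusted p = 0.0851, 0.204 and 0.609 with an estimated correlation. The unfolded protein response (median -0.14, adjusted p 3.8e-07), immediate early (median -0.17, adjusted p 1.94e-05), matrix (median -0.20, adjusted p 4.77e-05) and basal (median -0.20, adjusted p 0.000154) lists were lower too, against adjusted p = 0.3, 0.3, 0.204 and 0.393 with an estimated correlation. The axoneme list had a median change of 0.62 (adjusted p 3.11e-16) and the intraflagellar transport list of 0.20 (adjusted p 9.31e-05), against adjusted p = 0.568 and 0.708 with an estimated correlation. The 3 genes that passed were all lower. With limma, 0 genes were higher, 308 were higher at an unadjusted p under 0.05, and 34 genes passed with donor as a block, 7 higher and 27 lower. Without day 14 replicate 1, day 14 replicate 3 or day 8 replicate 3 the count was 1, and it was 5 without day 8 replicate 2. RHOF lost its call with each array centred on its median (-0.81, adjusted p 0.0652) and over the mean of its probe sets (-0.29, adjusted p 0.975). GDF15 lost its call over the mean of its probe sets (-0.70, adjusted p 0.073).

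From day 14 to day 28 the genes named were ABCA13, a lipid transporter near the limit for dim genes on day 14, at 1.78 ± 0.33 or higher, PNMA6A at 1.23 ± 0.23 and HLA-DMB, which loads peptides onto MHC class II, at 0.74 ± 0.12 as rises. CAVIN2, a protein of caveolae, fell by 1.03 ± 0.18, the laminin chain LAMB1 by 0.87 ± 0.13, GALNT6 by 0.74 ± 0.12, EPAS1, a hypoxia-inducible transcription factor, by 0.71 ± 0.13 and DDIT4, a stress-induced inhibitor of mTOR, by 0.70 ± 0.10. EPAS1 lost its call with quantile normalization, with centred arrays and over the mean of its probe sets (-0.63, -0.70 and -0.66, adjusted p 0.118, 0.125 and 0.0902). LAMB1 lost its call with centred arrays (-0.86, adjusted p 0.0575). Hypoxia (median -0.18, adjusted p 1.73e-11), ribosomal protein (median -0.10, adjusted p 1.87e-08), basal (median -0.25, adjusted p 3.23e-05) and cholesterol (median -0.22, adjusted p 0.00746) lists were lower, against adjusted p = 0.156, 0.547, 0.33 and 0.704 with an estimated correlation. The axoneme (median 0.28, adjusted p 1.3e-08) and interferon (median 0.14, adjusted p 2.29e-06) lists were higher, against adjusted p = 0.69 and 0.33 with an estimated correlation. The cholesterol and interferon lists did not move steadily between these days. The mean change of the cholesterol list from day 0 was -0.92 ± 0.09 on day 14 (SD, n = 3). It was -0.37 ± 0.12 on day 21 and -1.12 ± 0.48 on day 28. In donor 3 that list was higher on day 28 (-0.57) than on day 14 (-0.82). The interferon list stood at 0.58 ± 0.12, 0.33 ± 0.09 and 0.735 ± 0.271 on days 14, 21 and 28. The squamous list was called higher (median 0.23, adjusted p 1.36e-07, against adjusted p = 0.609 with an estimated correlation), but without day 28 replicate 3 it pointed lower and was not called (adjusted p 0.291). Oxidative phosphorylation (median -0.07, adjusted p 0.0232), unfolded protein response (median -0.09, adjusted p 0.0436) and tight junction (median 0.02, adjusted p 0.0461) lists lost their calls with the donor block (adjusted p 0.0519, 0.0737 and 0.0573). With an estimated correlation their adjusted p-values were 0.879, 0.704 and 0.69. The unfolded protein response list also lost its call with genes on 1 list only (adjusted p 0.182). The tight junction list lost its call without day 28 replicate 3 (adjusted p 0.401). The matrix, intraflagellar transport and secretory lists were called with the block (adjusted p 0.0086 lower, 0.0239 higher and 0.0114 lower), against adjusted p = 0.41, 0.902 and 0.614 with an estimated correlation and the block. Without the block, the matrix list was called with genes on 1 list only (adjusted p 0.0487) or without day 1 replicate 1 (adjusted p 0.048). The intraflagellar transport list was called without day 28 replicate 3 (adjusted p 1.24e-05). With an estimated correlation and all arrays these 2 lists had adjusted p = 0.605 and 0.906.

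In all, 10 genes passed between day 14 and day 28, 3 higher and 7 lower, and 53 passed with donor as a block, 13 higher and 40 lower. The split was 4 higher and 5 lower with quantile normalization and 3 and 3 with centred arrays. Without day 14 replicate 3 or day 28 replicate 2 limma called 0 genes, with 609 and 692 at an unadjusted p under 0.05. It called 1 gene without day 14 replicate 2 and 4 without day 28 replicate 1, and over all arrays 794 genes lay at an unadjusted p under 0.05.

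**Figure D3:**
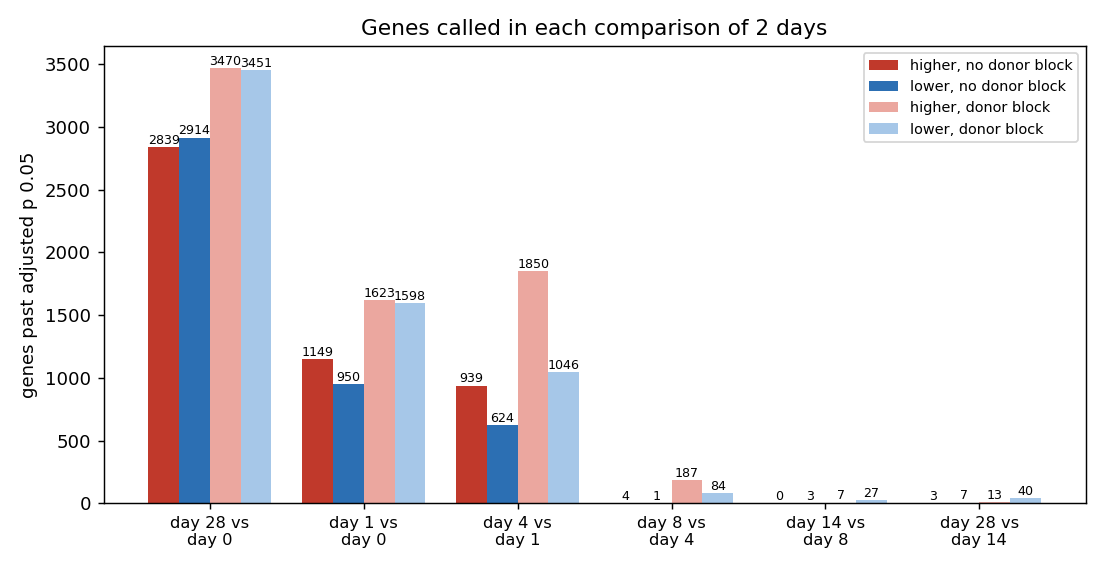
Number of genes past an adjusted p of 0.05 (y axis) in each comparison of 2 days (x axis), higher or lower on the later day, without and with donor as a block. Day 28 against day 0 gave 2839 higher and 2914 lower genes without the block, and day 8 against day 4 gave 4 and 1 without it and 187 and 84 with it.

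Over all 11 days, 5673 of 16036 genes changed by the moderated F test. A smaller group was higher or lower in the mean of days 4, 8 and 10 than on both day 0 and day 28. The other days were not compared, so these genes need not be highest or lowest in the middle of the culture. Against both day 0 and day 28, 209 genes differed in the same direction from the mean of days 4, 8 and 10, with 195 that peaked and 14 that dipped. TCIM, a regulator of Wnt signalling, was higher on those days by at least 3.57 ± 0.42 against day 0, where it was at or below the limit for dim genes on 2 of 3 arrays, and by 1.55 against day 28. GAS1, a membrane protein of Hedgehog signalling, was higher by 2.71 ± 0.37 and 1.85, RARRES1, a gene induced by retinoids, by 2.32 ± 0.28 and 1.91, and the claudin CLDN10 by 1.83 ± 0.34 and 2.17. CYP26A1 was higher by 1.73 ± 0.30 and 2.88, and the chemokine CXCL2 by 1.71 ± 0.35 and 1.38. The dips named were DMKN, a secreted epidermal protein, at -1.93 ± 0.26 and -0.81, GDPD3 at -1.68 ± 0.27 and -1.07, MAP7D2, at or below that limit on 4 of the 9 middle arrays, at -0.89 ± 0.16 and -0.59 or lower, SMIM5 at -0.84 ± 0.14 and -0.77, CTNNAL1 at -0.66 ± 0.14 and -0.50, and LINC01133 at -0.53 ± 0.16 and -0.50. LINC01133 lost its call against day 28 with quantile normalization, with centred arrays and over the mean of its probe sets (-0.50, -0.51 and -0.27, adjusted p 0.0543, 0.0515 and 0.119). DMKN lost its call against day 28 with the trend and robust options of eBayes (-0.81, adjusted p 0.0535). With donor as a block 452 genes were called, and the peaks and dips were 119 and 40 with quantile normalization and 114 and 30 with centred arrays. Without day 28 replicate 1 or day 28 replicate 2, 84 and 94 genes were called, and 14 without replicate 2.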

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

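Tests of leukocytes, of 1 cross-hybridizing probe set, of a general interferon response, of donor timing, of fibroblast genes by replicate and of days reassigned within donors were chosen after the results they concern had been seen, and the tests of the spread of ciliary genes before theirs.

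The cell cycle lists stood out because their change from day 0 went in opposite directions at day 1 and day 28. The mitosis list changed by a mean of 0.74 at day 1 and -1.25 at day 28, a difference of -1.98 ± 0.57 (SD over 3 donors, below 0 in 3 of 3). Camera on the difference itself gave an adjusted p of 4.14e-39 with the preset correlation and 0.0727 with an estimated one. The S-phase list changed by 0.81 and -0.36, a difference of -1.17 ± 0.36 (below 0 in 3 of 3 donors), with adjusted p-values of 2.71e-28 and 0.0727. Both lists were picked for these opposite changes, so the tests of the difference add no independent support. No explanation was tested.

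A signal outside the gene measurements appeared in the control probe sets. On the array of day 1 replicate 1, the mean of 27 probe sets for bacterial control transcripts was 5.72 on the log2 scale, 1.48 above the median of the other 29 arrays, and each of the 27 was above all other arrays. The 18S ribosomal RNA probe sets lay 1.05 above the median there, and the 18 hybridization control probe sets 0.28 above. Without that array, 1690 genes passed between day 0 and day 1 and 1509 between day 1 and day 4.

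Without the donor block, few genes passed from day 4 to day 8, although the axoneme list was higher by a median of 2.22-fold. None of the axoneme genes passed with limma in that fit (57 of 106 higher at an unadjusted p under 0.05). Noise of single arrays is argued against, because the residual SD of 106 axoneme genes over days 4, 8 and 10 was 5.05 times that of genes of similar level (3.45 to 6.51 with a donor left out). Constant differences in level between donors are argued against as the whole cause, because with the replicate block that ratio was still 3.77 (2.53 to 4.31), although the block raised the count from 5 to 271. That donors differed in the day on which ciliary genes rose stays open as a hypothesis. The SD of the axoneme list over donors was 1.68 times as large on day 8 as on day 28, from 3 donors only. The list reached 50% of each donor's own day 28 change at 5.63, 7.66 and 9.6 days in replicates 1, 2 and 3. Intraflagellar transport genes did so at 4.7, 6.67 and 9.9 days, in the same order. The axoneme list rose least by day 8 (0.53 against 1.31 and 2.22) in replicate 3. There 7 fibroblast genes changed from day 0 by a mean of 0.566 on day 4 and 0.644 on day 8, against -0.089 to 0 in the other replicates. POSTN, LUM and DCN made up most of it (2.65, 1.12 and 0.71 on day 8), while COL1A1 and COL1A2 had 0.24 and -0.18 and the median of the 7 was 0.238. A share of fibroblasts or a change of state in that culture stays open too. On day 28 the axoneme list stood at 2.53, 2.40 and 1.60 in replicates 1, 2 and 3. Whether a difference between donors in the final level, or between cultures of 1 donor, played a part was not tested.

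MHC class II genes rose from day 0 to day 28. Of 8 genes, class II genes and their chaperone CD74 together, 6 rose on probe sets of their own, which argues against 1 cross-hybridizing probe set: HLA-DRA by at least 6.06 ± 0.33, from the limit for dim genes on day 0, CD74 by 4.56 ± 0.29, HLA-DPA1 by 4.26 ± 0.55, HLA-DMA by 3.16 ± 0.29, HLA-DPB1 by 1.49 ± 0.25 and HLA-DMB by 1.47 ± 0.12, while HLA-DOA and HLA-DOB had -0.01 ± 0.12 and -0.02 ± 0.16. Leukocytes in the cultures are argued against, because 5 pan-leukocyte genes had a median change of 0.185, although ITGB2 rose by 0.77 ± 0.29. Of the 5, PTPRC at 5.94 and TYROBP at 4.14 on day 28 lay below the limit of 6.05 set for dim genes and were not tested. CD53, LAPTM5 and HCLS1 lay above it, at 7.32, 7.34 and 8.9. Their changes of -0.17 ± 0.10, 0.24 ± 0.12 and 0.41 ± 0.24 did not pass, while LAPTM5 and HCLS1 were higher in all 3 donors. A general interferon response stays open. The interferon list changed by 0.735 ± 0.271 (SD, n = 3), or 0.28 times the 2.62 ± 0.14 of all 8 genes (0.203 to 0.374 by donor), and its 27 risen genes by 0.336 times the 3.50 ± 0.16 of the 6 risen genes. How strongly each gene responds to interferon was not measured, so these ratios do not decide. HLA-F rose by 0.95 ± 0.17 and TAP1 had -0.06 ± 0.16. A rise within the epithelial cells as culture time went on also remains a hypothesis, and CIITA, the master regulator of class II genes, had a change of 0.15 ± 0.08 that did not pass (adjusted p 0.131).

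Other splits of the same samples were counted for each fitted result. Chance was excluded for any change over time, where 1 of 100 assignments of the days, the real one, gave as many as 5673 genes and the highest of the others gave 1099. These assignments ignored the donors; with days reassigned within each donor, again 1 of 100 gave as many, and the highest of the others gave 194. For genes that peak or dip, 1 of 100 gave as many as 209 and the highest of the others gave 6. With days reassigned within donors the highest of the others gave 64, and 1 of 100 gave as many too. Reassigning days also mixes genes that rise or fall steadily over the groups, which widens the spread in the fit. These assignments therefore ask whether days differ at all, and cannot show that 209 peaks and dips exceed chance beside steady changes. A comparison of 3 with 3 samples has 10 splits, too few for a share under 0.05. The real values and the highest of the other splits were 5753 and 131 for day 28 against day 0, 2099 and 63 for day 1 against day 0, 1563 and 0 for day 4 against day 1, and 3 and 0 for day 14 against day 8, each with 1 split as large. For day 8 against day 4 they were 5 and 27, and for day 28 against day 14 they were 10 and 18, each with 2 splits as large. In both, the larger value came from 1 of 6 splits that did not part all 3 donor pairs and so mixed donor with day. The rest of these 6 gave 0 genes, and 1 split cannot show a cause. The 3 other splits that parted all pairs gave fewer genes than the real one. For day 1 against day 0 the highest other value also came from a split that did not part all pairs, and for day 28 against day 0 from one that did, while the 6 that did not gave at most 2. With donor as a block, day 8 against day 4 gave 271 genes and day 28 against day 14 gave 53.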

How the results depend on the processing

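The alternatives of list tests without day 1 replicate 1, without day 28 replicate 3 and with both an estimated correlation and the replicate block were chosen after seeing the data. Quantile normalization, no filter on dim genes, eBayes with trend and robust options and an offset of 16 left each total count of genes within 1.5 times of its value, while quantile normalization moved the numbers of peaks (119) and dips (40) by more. With the replicate block 3221 genes passed for day 1 against day 0, 2896 for day 4 against day 1, 271 for day 8 against day 4, 34 for day 14 against day 8, 53 for day 28 against day 14, and 452 peaked or dipped. The block left the count for day 28 against day 0 (6921) and for any change (7649) within 1.5 times, all 5753 and 5672 of 5673 genes were called in both fits, and among the named genes and lists it changed no call beyond those given above. As a random block it gave 2577 for day 4 against day 1, then 93, 9 and 19 for the later intervals in order, and 393 peaks or dips. Array quality weights gave 9370 genes for any change, 3359, 5054, 1178 and 167 for day 1 against day 0, day 4 against day 1, day 8 against day 4 and day 28 against day 14, and 600 peaks or dips. Every probe set by itself gave 9714, 10339, 3441 and 2414 for any change, day 28 against day 0, day 1 against day 0 and day 4 against day 1, and 315 peaks or dips, because more features were tested. A 2-fold threshold left, by construction, 1471 for day 28 against day 0, 188 for day 1 against day 0, 333 for day 4 against day 1, 2 for day 8 against day 4, 3 for day 28 against day 14 and 10 peaks or dips. With only the days compared, and so fewer samples, the counts were 711 for day 1 against day 0, 666 for day 4 against day 1, 0 in each later interval (936, 739 and 757 at an unadjusted p under 0.05 with limma) and 118 peaks or dips. For day 8 against day 4, centred arrays gave 13, the 60th percentile filter 13 and the mean of all probe sets 3. Centred arrays gave 6 for day 28 against day 14, and the mean of all probe sets gave 0 for day 14 against day 8 with limma (721 at an unadjusted p under 0.05). For the block, the weights, centring, the 60th percentile filter and the mean of probe sets the cause was not tested. Of the 65 list calls, 4 held with an estimated correlation and 0 with an estimated correlation and the replicate block. Over all 156 tests fry called 39, of which 31 were among the 65. CFAP73 reversed from day 0 to day 28 over the mean of its probe sets (0.23, adjusted p 0.182), and the squamous list reversed from day 14 to day 28 without day 28 replicate 3 (adjusted p 0.291, against 1.42e-07 without day 1 replicate 1); the cause was not tested. Of 174 values of named genes, 174 kept direction and call with an offset of 16, 173 with the block, 172 with trend and robust options, 169 with quantile normalization, 168 with centred arrays and 154 over the mean of probe sets; 38, 54 and 22 lost their call without replicates 1, 2 and 3. Leaving out a donor or an array gave 1201 to 5928 genes for any change, 2531 to 6331 for day 28 against day 0, 70 to 2584 for day 1 against day 0, 251 to 1686 for day 4 against day 1, 0 (583 at an unadjusted p under 0.05 with limma) to 64 for day 8 against day 4, 1 to 5 for day 14 against day 8, 0 (340 to 1142 unadjusted with a donor left out) to 14 for day 28 against day 14 and 14 to 305 for peaks and dips, and 65 to 67 list calls. The lowest count for any change, day 28 against day 0, day 1 against day 0, day 4 against day 1 and peaks and dips came without replicate 2. Leaving out replicate 2 or replicate 3 each leaves 1 sample on days 2, 12 and 17, assumed to vary like the others. Without replicate 3 none of these counts fell as far, so fewer samples alone do not account for it. Replicate 2 lay between the other donors in the axoneme list on day 8 (1.31, against 2.22 and 0.53). A fit without it and without a donor block keeps the more different donors, so these counts do not show that the changes rest on replicate 2. Without day 28 replicate 3, 5730 genes passed for day 28 against day 0. Signal over background limits dim genes, whose changes RMA compresses.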

Other observations

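Genes with a shared symbol stem, tested after seeing the data, included groups that no list covered. Over 190 stems of at least 10 genes and 1140 one-sided Fisher's exact tests, 26 passed an adjusted p of 0.05. Stems such as CFAP, IFT, DRC, DNAAF, MCM, KIF, CDC and RPL hold genes of kinds that lists cover. Of all genes tested, 7.17% rose and 5.92% fell from day 0 to day 1. From day 0 to day 1 the 10 stems with more rises than other genes included several of ribosome production, transcription, and transport into mitochondria or nucleus, besides MCM and ALG, and 30 of 199 TMEM genes fell (adjusted p 0.000206). Of 49 MRPL genes, which encode proteins of the mitochondrial ribosome, 18 rose (median 0.23, adjusted p 1.69e-06), with MRPL3 at 0.67 ± 0.11 and MRPL12 at 0.67 ± 0.11. Of 10 UTP and 10 NOL genes, which act in the nucleolus, 7 and 7 rose (adjusted p 9.77e-05 for each), with UTP15 at 0.83 ± 0.18 or higher and NOL6 at 0.77 ± 0.15. Of 31 DDX helicases 12 rose, with DDX21 at 0.99 ± 0.19 (adjusted p 9.77e-05), and of 31 POLR subunits of RNA polymerases 11 rose, with POLR1B at 1.05 ± 0.17 (adjusted p 0.000412). Of 15 TIMM genes 8 rose, with TIMM8A at 0.98 ± 0.17, of 25 NUP genes of the nuclear pore 10 rose, with NUP35 at 0.97 ± 0.19, and of 10 EXOSC genes of the RNA exosome 6 rose, with EXOSC9 at 0.65 ± 0.12 (adjusted p 0.000243, 0.000337 and 0.00156). The medians of these stems kept their direction with quantile normalization and with centred arrays. Genes are not independent replicates.

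From day 0 to day 28, 113 of 400 ZNF zinc finger genes rose (median 0.13, 0.08 with quantile normalization and 0.04 with centred arrays, adjusted p 2.11e-05), with ZNF91 at 1.61 ± 0.15 and ZNF112 at 1.56 ± 0.23 or higher. UTP15 and ZNF112 were at or below the limit for dim genes on 2 of 3 arrays of day 0. Of 11 COQ genes, many of which act in coenzyme Q synthesis, 7 rose, with COQ8A at 1.65 ± 0.20 (adjusted p 0.0435). Of all genes tested, 17.7% rose from day 0 to day 28. The classical MHC class I genes HLA-B and HLA-C rose by 1.32 ± 0.12 and 0.86 ± 0.11 and B2M by 0.62 ± 0.08, and the class I gene HLA-F rose by 0.95 ± 0.17. HLA-E and the peptide transporter TAP1 had -0.15 ± 0.09 and -0.06 ± 0.16 and did not pass (adjusted p 0.189 and 0.798). These genes were chosen after their values were seen.

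The regulators of ciliated cells reached 50% of their day 28 change earlier than the axoneme list in 3 of 3 donors, by 1.78 to 3.26 days on the mean of the list and by 2.4 to 4.27 days on its median. Without CDC20B, which rose early, the mean was earlier by 0.21 to 3.09 days. From day 1 to day 4 the 2 lists had medians of 0.15 and 0.16, so the typical regulator moved no more than the typical axoneme gene in that interval. With 3 donors an exact sign-flip test cannot give a two-sided p under 0.25, and the order is given as a description.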
